A study of Homo sapiens with 94 samples.

How the data were processed

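Total RNA was sequenced after ribosomal RNA depletion with a stranded kit, and nascent RNA by PRO-cap (5' ends of capped nascent transcripts) and PRO-seq (engaged polymerase), per the labels' protocols. The labels give 63 total RNA, 9 PRO-cap and 9 PRO-seq samples, with 3 replicates in every group of these, and 13 DNA samples that were not used here because no table read here holds their values. Groups were read from the labels: untreated, Aza (880 nM in HEK293 and 55 nM in U2OS, 48 h), doxycycline (1 µg/mL, 48 h), thio (25 µM, 48 h), UVA (10 kJ/m² every 8 h, 4 times) and UVA with thio. The 37 tables, 26 of total RNA and 11 of nascent RNA, each hold comparisons of groups and no value per sample, so nothing could be refitted.

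Per the submitters' processing notes, reads were handled with Trim Galore 0.4.3, STAR 2.4.2, Bowtie2 2.2.6, SAMtools 0.1.19, Picard 1.139, bedtools 2.20.1 and deepTools 3.0.2 on hg19, with chicken galGal5 spike-in for nascent RNA, and R 3.5.1 and DESeq2 1.22.1 are named without a stated role. The signal values that the authors deposited are mean normalized counts per gene or site over the libraries of an experiment (the column baseMean). The log2 values that the authors deposited are fold changes of treated over untreated cells and their standard errors. In the total RNA tables these are shrunken toward 0, as the values show, since the p-value is not that of the fold change over its standard error; the method is not stated. The p-value columns that the authors deposited hold raw values and adjusted values, blank where genes had been filtered. The score column that the authors deposited in the nascent tables is the fold change over its standard error. Columns named as outlier marks, 12 in all, have no stated meaning and were not used here.

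Genes were called at an adjusted p below 0.05 as deposited. The depth of each sample is not given in the tables: the median mean level stands in its place, from 4.98 at dispersed antisense start sites to 1000 in sense total RNA of U2OS. Of 18850 genes in each total RNA table, 70 symbols occurred more than once, and the copy with the highest mean level was kept. The planned test of a difference between effects used the deposited values, but these proved to be shrunken. The shrinkage was therefore undone under a Cauchy prior whose scale was fitted to the p-values, and the difference of unshrunken values was tested by z with adjustment over all genes. For G37 with doxycycline the standard errors could not be recovered, and the geometric mean of those in the other lines was used. The test takes the effects as independent, so effects that share untreated libraries were not subtracted, and the interaction of UVA and thio was formed from comparisons with separate groups, UVA with thio against thio, and UVA against untreated. On 12930 genes the deposited comparison of UVA with thio against UVA equalled the difference of the unshrunken effects with a correlation of 0.9999.

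The code was tested on simulated data with 12884 genes of which 200 were changed. Of genes changed by 0.25, 0.5, 1 and 2 on log2, the test called 56%, 88%, 96% and 100%, and 8.60% of calls were unchanged genes. The list test gave a p of 0.000128 for a shifted list of 30 and a p below 0.05 for 2.5% of 200 unshifted lists.

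The comparisons, the rule for naming genes and 27 gene lists were fixed before the data were examined. In each sense comparison the called genes with a mean level of at least 100 and a symbol that is no clone name were ranked by fold change, and the 8 largest of each direction were named for 6 comparisons (doxycycline with TET-CD, with TETmut-CD and in U2OS, Aza in HEK293 and in U2OS, and UVA with thio) and 3 for all others. Genes of the methyl-binding, TET and DNMT1 set and up to 4 members per list were added. The dispersed start sites had a mean level too low for names. Some genes that the rule names are not reported here. The lists were p53 targets, interferon response, integrated stress response, unfolded protein and heat shock, NRF2 targets, immediate early, NF-kB cytokines, S phase, G2 and M phase, cholesterol synthesis, nuclear oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosomal proteins, replication-dependent histones, cytosine methylation machinery, cancer-testis, germline, imprinted, neuronal, mesenchymal, epithelial and blood markers, polycomb targets, housekeeping, ZNF zinc fingers, clustered protocadherins and mitochondrially encoded genes, of which 0 were in the tables.

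Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on signed z-values at a preset correlation of 0.01, adjusted over lists within a comparison. An estimated correlation for list tests could not be had, since no per-sample values exist, and a preset correlation of 0.05 was used in its place as an alternative, beside a test on ranks. Member counts are given over all genes tested and adjusted over the list alone. Shares of higher calls carry exact binomial 95% intervals and were compared with primary sites by Fisher's exact test. Slopes and correlations carry 95% intervals from 1000 bootstrap draws over genes. Overlaps of calls were set against independence and, where untreated libraries were shared, against 100 simulations of control noise alone. Simulated genes carried no treatment effect, so of these figures only the covariance is comparable with the data. In the total RNA pairs given here the shared part of the noise was assumed. The untreated libraries cannot be split between comparisons without values per sample. Other alternatives were adjustment over every gene with a p, a mean level of at least 50, centring on the median gene, and an adjusted p below 0.01. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.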

Results

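Total RNA and nascent RNA were compared between treated and untreated HEK293 and U2OS T-Rex Flp-in cells, lines in which doxycycline switches on an integrated construct. The constructs were TET-CD-GFP, the catalytic domain of a TET dioxygenase (an enzyme that oxidises 5-methylcytosine) fused to GFP, and its mutant form TETMut-CD-GFP, called TET-CD and TETmut-CD here. Other cells received 5-aza-2'-deoxycytidine (Aza), a cytidine analogue that traps DNA methyltransferases, or 4-thio-2'-deoxythymidine (thio) and UVA light, alone and together. The series held 94 samples: 63 of total RNA, 9 of PRO-cap, 9 of PRO-seq and 13 of DNA, with 3 libraries per group of total or nascent RNA. The DNA samples were not analysed here. All fold changes are log2 values with their standard errors from 37 authors' deposited tables, whose columns are those of DESeq2, a tool named in the submitters' processing notes, and a gene was called at an adjusted p below 0.05. The p-values measure spread between these samples of a line. Genes with the largest changes are named from those with a mean level of at least 100.

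Induction of TET-CD in HEK293 raised TET1, a TET dioxygenase gene, by 2.34 ± 0.03 in the authors' deposited table, which does not separate transcripts of a construct from endogenous ones. Among called genes at that level the next largest rises there were in CTSH, a lysosomal protease (0.67 ± 0.15, adjusted p = 8.2e-05), RPP25, a subunit of RNase P (0.67 ± 0.15), and HSPA2, a chaperone prominent in testis (0.67 ± 0.18). HIST1H2BG, a histone H2B gene (0.65 ± 0.09, adjusted p = 2.6e-10), GDF15, a secreted stress cytokine (0.64 ± 0.18), ERVMER34-1, an endogenous retroviral envelope gene (0.62 ± 0.11), and CPT1C, a carnitine palmitoyltransferase (0.61 ± 0.18), followed in the authors' deposited table. Among called genes VPS9D1, which encodes a VPS9 domain protein, fell most (-0.72 ± 0.08, adjusted p = 4.5e-19) in the authors' deposited table. It was followed by KIAA1199, a hyaluronan-binding protein gene (-0.63 ± 0.14), MANEAL (-0.37 ± 0.04), PHF21B (-0.27 ± 0.07) and the NAD hydrolase gene SARM1 (-0.27 ± 0.04), per the authors' deposited table. Smaller falls there were in BMP6, a secreted growth factor gene (-0.19 ± 0.05), the helicase gene RTEL1 (-0.17 ± 0.05) and the overlapping RTEL1-TNFRSF6B (-0.15 ± 0.05). KRT19, an epithelial keratin gene, rose by 0.38 ± 0.05 and GSTP1, a detoxification enzyme gene known to be silenced by methylation in prostate cancer, by 0.33 ± 0.04 in the authors' deposited table. In all, 98 genes were higher and 34 lower of 15000 tested, with a median mean level of 698.

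With TETmut-CD, TET1 rose by 1.98 ± 0.03 in the authors' deposited table, while the shrunken values of KRT19, GSTP1 and VPS9D1 each stood at 0.00 with standard errors of 0.02. SMARCD3, a chromatin remodeller subunit gene (0.41 ± 0.07), and ERC1, a presynaptic scaffold gene (0.15 ± 0.03), were higher in the authors' deposited table. The homeobox gene HOXA13 (-0.19 ± 0.04) and UQCRFS1, a respiratory complex III subunit gene (-0.18 ± 0.03), were lower in the authors' deposited table. These 5 genes were the only calls, 3 higher and 2 lower, among 18163 tested. The difference between the constructs' effects was tested directly from unshrunken values: 19 genes had the higher change with TET-CD and 6 the lower, of 15868 (38 and 7 from deposited shrunken values). VPS9D1 differed by -0.78 ± 0.11 (adjusted p = 1.1e-09), HIST1H2BG by 0.79 ± 0.13, ERVMER34-1 by 0.74 ± 0.15, and HIST1H2AE by 0.48 ± 0.10. Further differences were those of KRT19 (0.38 ± 0.07), GSTP1 (0.32 ± 0.06), MANEAL (-0.33 ± 0.06) and SARM1 (-0.28 ± 0.06). CTSH (0.69 ± 0.20, adjusted p = 0.19), RPP25 (0.72 ± 0.20, adjusted p = 0.13) and HSPA2 (0.83 ± 0.24, adjusted p = 0.16) did not pass. Nor did CPT1C (0.70 ± 0.24, adjusted p = 0.49), GDF15 (0.46 ± 0.25, adjusted p = 0.999) and KIAA1199 (-0.73 ± 0.20, adjusted p = 0.12). The same held for BMP6 (-0.26 ± 0.07, adjusted p = 0.12), RTEL1 (-0.16 ± 0.06, adjusted p = 0.77) and RTEL1-TNFRSF6B (-0.15 ± 0.06, adjusted p = 0.94). Of the TETmut-CD calls, SMARCD3 (-0.37 ± 0.10, adjusted p = 0.12), HOXA13 (0.18 ± 0.05, adjusted p = 0.26) and UQCRFS1 (0.08 ± 0.04, adjusted p = 0.999) did not pass either. TET1 itself differed by 0.36 ± 0.04, so the TETmut-CD line carried somewhat less of that transcript's rise. Over the 131 called genes other than TET1, the TETmut-CD changes had a slope of 0.00489 (95% interval -0.0680 to 0.0821) on the TET-CD changes, with a median standard error ratio of 1.00.

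**Figure D1:**
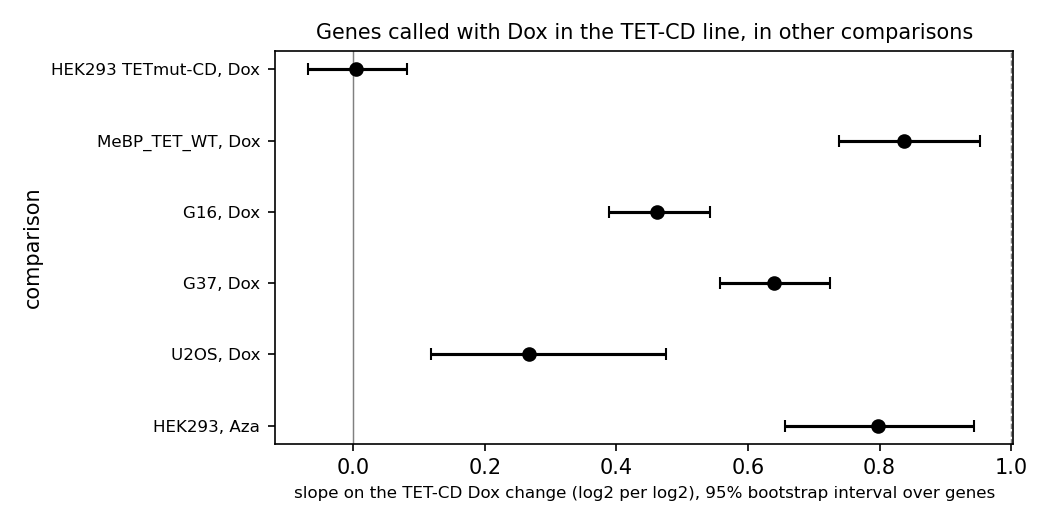
Slope, with 95% interval, of the change in each other comparison on the TET-CD doxycycline change, over genes called with TET-CD in HEK293.

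Of 20 measured epithelial marker genes only KRT19 was called higher with TET-CD, 3 rose when adjusted over the list alone, and the list test gave an adjusted p of 5.4e-07. This list was also higher in the direct difference between constructs (adjusted p = 6.5e-06). So were genes of G2 and M phase (adjusted p = 0.00052), which had fallen with TETmut-CD as a list (adjusted p = 5.8e-09) without a called member. The cytosine methylation machinery passed with TET-CD (29 genes, 1 higher, and 2 higher with 1 lower when adjusted over the list alone, adjusted p = 2.4e-08). TET1 carried this result, since the remaining genes gave a list test p of 0.50, not adjusted over lists. Clustered protocadherins (adjusted p = 0.0018, without a called member) and p53 targets (1 of 33, 2 adjusted over the list alone, adjusted p = 0.0041) passed as higher lists with TET-CD, yet at the correlation of 0.05 each p became 0.096. DNMT1, the maintenance methyltransferase gene, was not called (-0.08 ± 0.03, adjusted p = 0.071), and MYC was lower by -0.11 ± 0.04 in the authors' deposited table.

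Aza in HEK293 raised STAT6, a transcription factor of interleukin 4 signalling (1.92 ± 0.17, adjusted p = 4.8e-27), and ACTA2, the smooth muscle actin gene (1.28 ± 0.14), in the authors' deposited table. Further rises there were in the proteoglycan gene CSPG4 (1.27 ± 0.14), the cAMP sensor gene RAPGEF3 (1.22 ± 0.16), GLIS1 (1.19 ± 0.22), YPEL3 (1.14 ± 0.17), RASSF4 (1.12 ± 0.15) and EDA2R, a receptor gene induced by p53 (1.06 ± 0.12). The neurotransmitter receptor genes GABBR2 (-0.91 ± 0.17) and GABRA5 (-0.63 ± 0.18) fell in the authors' deposited table. The kinase gene MATK (-0.89 ± 0.15), the growth regulator MYC (-0.78 ± 0.09) and the ephrin receptor gene EPHA8 (-0.71 ± 0.11) fell as well, per the authors' deposited table. SLC27A2 (-0.64 ± 0.07), HES4 (-0.64 ± 0.09) and AK5 (-0.60 ± 0.16) were also lower in the authors' deposited table. The counts were 1190 higher and 1183 lower of 16585 tested, 1313 and 913 after centring, with a median mean level of 656. DNMT1 was not called (-0.09 ± 0.04, adjusted p = 0.051), whereas MBD3, a member of the methyl-binding domain family, fell by 0.22 ± 0.05 (adjusted p = 9.5e-05) in the authors' deposited table.

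Of 33 measured p53 targets, 29 rose with Aza in HEK293, the same 29 when adjusted over the list alone (list test adjusted p = 1.4e-51). SPATA18 (0.90 ± 0.10), CDKN1A (0.78 ± 0.10), MDM2 (0.49 ± 0.05) and TNFRSF10B (0.41 ± 0.04) were among them in the authors' deposited table. Germline genes known to be silenced by promoter methylation rose (8 of 29, 11 adjusted over the list alone, adjusted p = 0.00022), with CTCFL at 5.02 ± 0.75 and GTSF1 at 6.74 ± 1.02 in the authors' deposited table. Cancer-testis genes did as well (5 of 28, 7 adjusted over the list alone, adjusted p = 0.00048), among them MAGEA11 (6.00 ± 0.90), also below that level, and TDRD1, whose value of 9.12 ± 2.59 in the authors' deposited table rests on few reads. Mesenchymal markers (10 higher and 1 lower of 29, the same adjusted over the list alone, adjusted p = 6.7e-05) rose. Epithelial markers did too (5 of 20, 6 adjusted over the list alone, adjusted p = 0.0015), with KRT19 at 0.88 ± 0.12 in the authors' deposited table. Genes of the mitochondrial ribosome were lower (11 of 30, 15 adjusted over the list alone, adjusted p = 7.1e-10), MRPS34 by -0.50 ± 0.06 in the authors' deposited table. Cytosolic ribosomal protein genes were lower as a list (1 higher and 6 lower of 81, 1 and 1 adjusted over the list alone, adjusted p = 7.2e-05). S phase genes were lower too (5 of 35, 5 adjusted over the list alone, adjusted p = 0.00048). Immediate early genes (9 higher and 1 lower of 29, 11 and 1 adjusted over the list alone, adjusted p = 0.0027) and NF-kB cytokine genes (3 of 22, 3 adjusted over the list alone, adjusted p = 0.0043) were higher. The interferon response list passed (7 of 31 higher, 7 adjusted over the list alone, adjusted p = 0.016) but at the correlation of 0.05 its p was 0.12, with IRF7 at 3.69 ± 0.67 in the authors' deposited table.

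**Figure D2:**
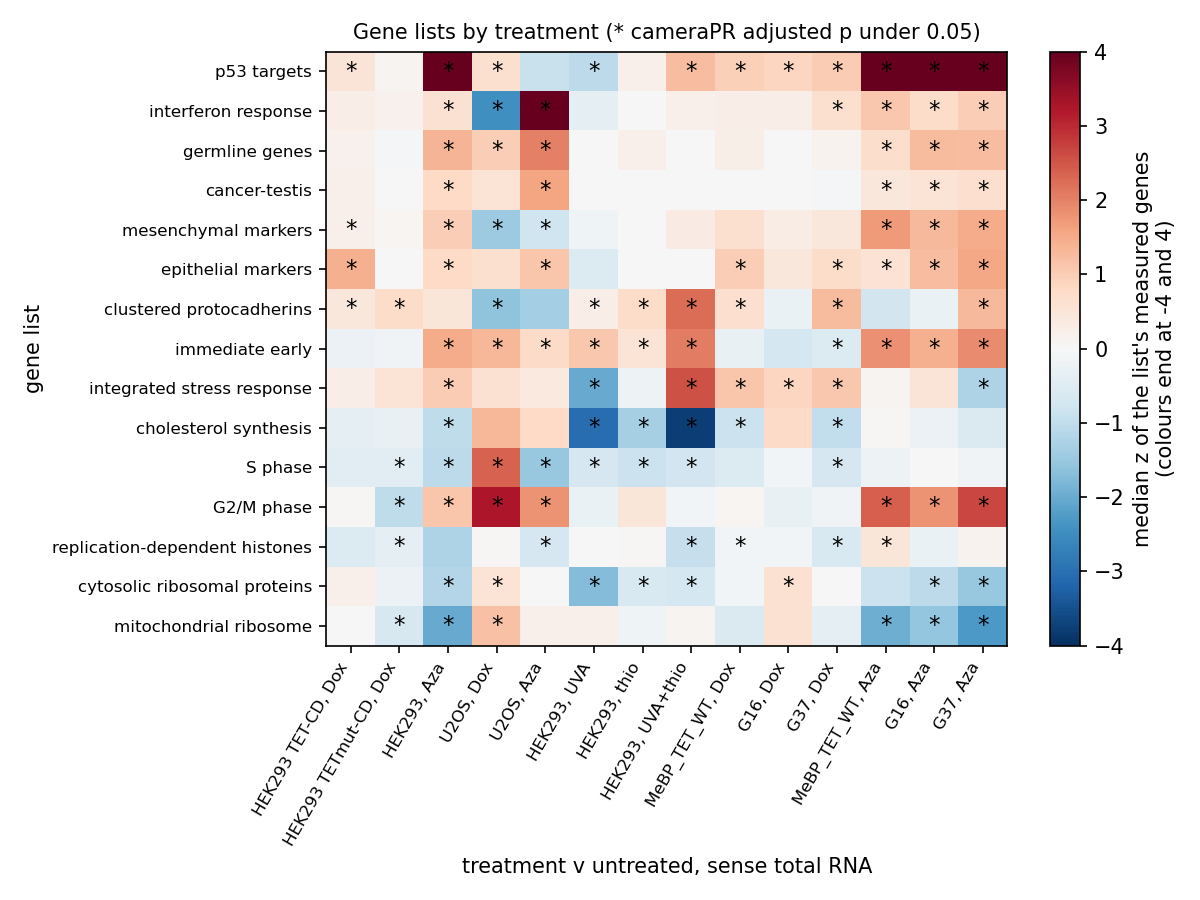
Fixed gene lists in sense total RNA comparisons, coloured by the median z of the list's measured genes and marked where the list test passed.

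The Aza and doxycycline effects in HEK293 differed directly in 716 genes. CLU, an extracellular chaperone gene, differed by 0.70 ± 0.09 toward Aza, CDKN1A by 0.78 ± 0.11, MDM2 by 0.44 ± 0.06 and TNFRSF10B by 0.42 ± 0.06. The ubiquitin ligase gene STUB1 (-0.50 ± 0.06), SLC27A2 (-0.66 ± 0.09) and TET1 (-2.47 ± 0.09) lay toward doxycycline. In all, 280 genes had the higher change with Aza and 436 the lower, but 410 and 404 from deposited shrunken values. The p53 targets lay toward Aza as a list (adjusted p = 6.7e-49) and the mitochondrial ribosome genes away from it (adjusted p = 7.9e-11). Genes called with TET-CD nevertheless moved alike with Aza: 52 were higher in each comparison, where 7.22 would be shared if calls were independent, and 18 lower, where 2.68 would be. Over the TET-CD calls the Aza changes had a slope of 0.797 (0.657 to 0.943) on the TET-CD changes, 113 of 131 having the same sign. The untreated libraries of these comparisons were different.

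In U2OS, an osteosarcoma line, Aza raised CTCFL, the germline relative of CTCF (4.61 ± 0.36), the Wnt antagonist gene DKK1 (3.20 ± 0.22), the focal adhesion gene TES (3.20 ± 0.17) and the proteoglycan gene VCAN (2.68 ± 0.14) in the authors' deposited table. INSL4, a placental hormone gene (2.48 ± 0.23), NLRP2 (2.39 ± 0.16), SALL3 (2.37 ± 0.25) and SHROOM4 (2.35 ± 0.19) followed in the authors' deposited table. The largest falls were in the chondroitin synthesis gene CSGALNACT1 (-0.92 ± 0.17), the basement membrane gene NID1 (-0.86 ± 0.04) and MARCH1 (-0.80 ± 0.10) in the authors' deposited table. Next came NTM (-0.79 ± 0.22), the cadherin gene CDH4 (-0.79 ± 0.12) and SLC12A7 (-0.79 ± 0.04), per the authors' deposited table. WWOX, a gene at a fragile site (-0.78 ± 0.15), and GPC1, a glypican gene (-0.78 ± 0.04), fell nearly as far in the authors' deposited table. DNMT1 (-0.18 ± 0.03, adjusted p = 1.8e-07), TET1 (-0.17 ± 0.03) and MBD3 (-0.17 ± 0.04) were lower and MBD4, a thymine glycosylase gene, was higher (0.19 ± 0.05) in the authors' deposited table. The counts were 1895 higher and 2266 lower, 2095 and 2072 after centring, at a median mean level of 1000.

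Interferon response genes rose with Aza in U2OS (22 of 30, 25 with 1 lower when adjusted over the list alone, adjusted p = 6.2e-21). IFI44 (0.83 ± 0.07), IFIT1 (0.82 ± 0.06), OASL (0.79 ± 0.07) and ISG15 (0.47 ± 0.04) were among them in the authors' deposited table. Germline genes rose (13 higher and 1 lower of 29, 14 and 1 adjusted over the list alone, adjusted p = 5.8e-09). Cancer-testis genes (12 and 1 of 35, 14 and 1 adjusted over the list alone, adjusted p = 0.00041) and G2 and M phase genes (12 of 30, 12 adjusted over the list alone, adjusted p = 1.8e-05) rose as well. Mesenchymal markers fell (4 higher and 11 lower of 29, 5 and 11 adjusted over the list alone, adjusted p = 9.7e-05), COL5A1 by -0.55 and CAV1 by -0.50 in the authors' deposited table. Housekeeping genes were lower (1 higher and 8 lower of 17, 1 and 9 adjusted over the list alone, adjusted p = 0.0022). Replication-dependent histone genes went in either direction (19 higher and 30 lower of 70, 21 and 32 adjusted over the list alone), passed as lower (adjusted p = 5.4e-05), and did not pass on ranks (adjusted p = 0.17). The p53 targets did not pass (1 higher and 9 lower of 33, 2 and 12 adjusted over the list alone, adjusted p = 0.094), and CDKN1A fell by 0.12 ± 0.03 in the authors' deposited table.

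Doxycycline in U2OS raised TET1 by 3.52 ± 0.03 and TES by 2.34 ± 0.17 in the authors' deposited table. PRAMEF4 (2.35 ± 0.24), PRAMEF11 (2.31 ± 0.19), PRAMEF6 (2.16 ± 0.19) and PRAMEF1 (2.04 ± 0.10), members of a family of near-identical cancer-testis genes among which reads are hard to place, followed in the authors' deposited table. ALPPL2, the germ cell alkaline phosphatase gene (2.30 ± 0.19), and MEIOB, a meiotic recombination gene (2.29 ± 0.14), rose similarly there, per the authors' deposited table. SLITRK5, a neuronal adhesion gene, fell most (-1.32 ± 0.10), then MLC1 (-0.92 ± 0.09) and the antiviral genes RSAD2 (-0.86 ± 0.14) and IFI44L (-0.70 ± 0.20), in the authors' deposited table. GPR112 (-0.61 ± 0.19), SCEL (-0.61 ± 0.16), RCAN2 (-0.59 ± 0.11) and OFCC1 (-0.56 ± 0.19) were lower by less in the authors' deposited table. The counts were 932 higher and 1032 lower, and after centring 1082 and 923, so the larger direction depended on scaling. No U2OS line with the mutant construct was in the series, so an effect of doxycycline itself was not separated here.

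The interferon response list fell with doxycycline in U2OS (2 higher and 13 lower of 30, 2 and 16 adjusted over the list alone, adjusted p = 9.8e-06), OASL by -0.48 ± 0.08 and IFIT2 by -0.49 ± 0.07 in the authors' deposited table. Genes of G2 and M phase rose (19 of 30, 23 adjusted over the list alone, adjusted p = 1.4e-16), with HMMR at 0.30 and UBE2C at 0.27 in the authors' deposited table. S phase genes did as well (13 of 35, 19 adjusted over the list alone, adjusted p = 3.1e-07). Clustered protocadherins, adhesion genes that share exons and so share reads, were lower (13 of 49, 13 adjusted over the list alone, adjusted p = 2.1e-07). Mesenchymal markers were lower (1 higher and 10 lower, 1 and 12 adjusted over the list alone, adjusted p = 1.4e-06) and immediate early genes higher (6 higher, 7 with 1 lower adjusted over the list alone, adjusted p = 0.00025). Heat shock and unfolded protein genes passed as higher (4 of 22, 4 adjusted over the list alone, adjusted p = 0.038) but not at the correlation of 0.05, where p was 0.15. For the cytosine methylation machinery in U2OS with doxycycline, the list passed (3 higher and 2 lower of 29, 3 and 3 adjusted over the list alone, adjusted p = 0.016) with a mean z of 1.10 and a median z of -0.04. At the correlation of 0.05 its p was 0.13. TET1, which doxycycline raised, is a member of this list, so the pass says nothing of the remaining genes. Imprinted genes passed in no comparison, the smallest adjusted p being 0.244 here (4 of 24 higher, 4 adjusted over the list alone).

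**Figure D3:**
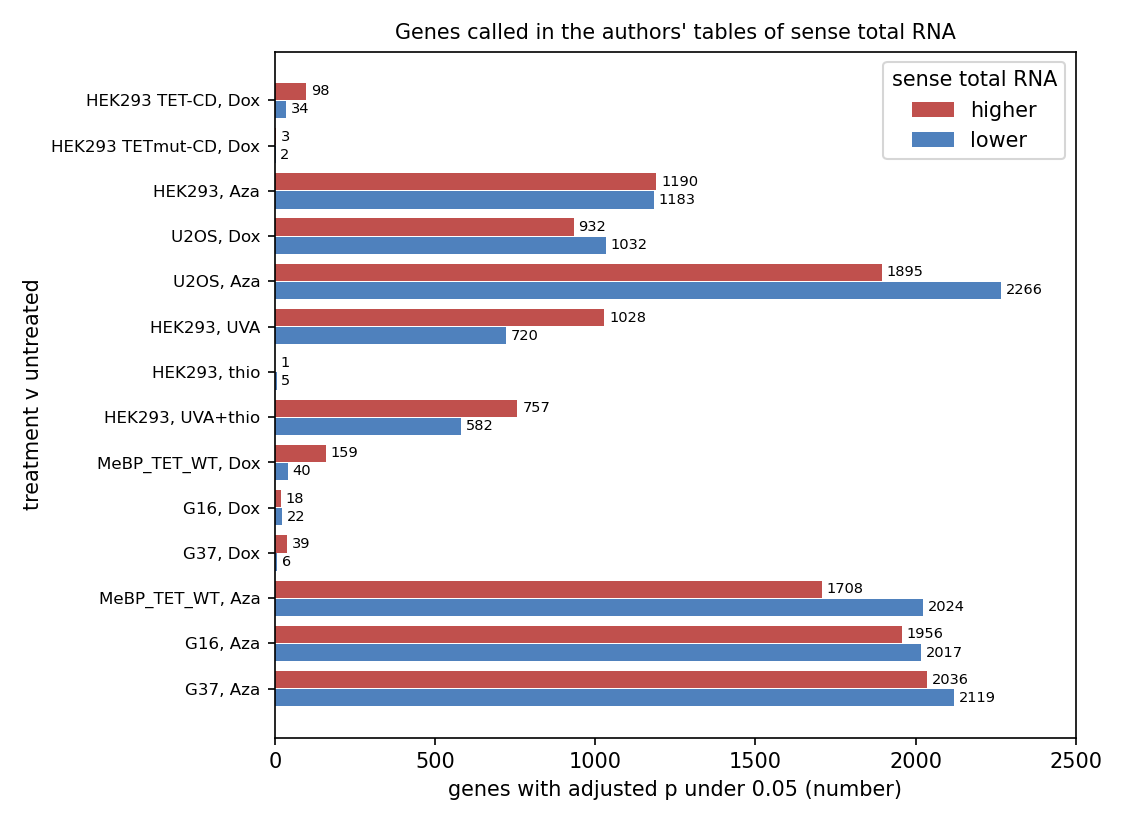
Genes higher and lower at an adjusted p below 0.05 in each sense total RNA comparison with untreated cells.

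Aza and doxycycline in U2OS shared TES, VCAN and the cytoskeletal gene BASP1, which rose by 1.96 ± 0.11 with Aza and 1.84 ± 0.11 with doxycycline in the authors' deposited table. In the authors' deposited table for HEK293, BASP1 rose by 0.20 ± 0.06 with Aza and was not called with doxycycline (0.01 ± 0.03), and TES was called with neither. Together 585 genes were higher in the U2OS comparisons and 715 lower, against 107 and 145 for independent calls, with 29 opposite and a correlation of 0.68. Untreated libraries were shared, and simulations of the shared control noise alone, taking as many top genes, gave 379 and 463 and a correlation of 0.493. Those simulated genes carried no effect, so these figures are not comparable with the data. The covariance is, at 0.0325 against at most 0.00487 simulated, with an assumed share of noise. The direct difference between the lines' doxycycline effects gave 182 genes higher and 184 lower in HEK293. It was negative in TES (-2.37 ± 0.17), VCAN (-1.88 ± 0.15), BASP1 (-1.82 ± 0.12), TET1 (-1.18 ± 0.04) and PNP (-0.75 ± 0.05), and ERC1 differed by 0.56 ± 0.05. For Aza the lines differed in 1073 genes toward HEK293 and 891 toward U2OS, with STAT6 (1.83 ± 0.17), CSPG4 (1.47 ± 0.15) and NFATC1 (1.43 ± 0.11) on the HEK293 side. On the U2OS side lay HIST1H4D (-3.99 ± 0.31), TES (-3.17 ± 0.17), VCAN (-2.71 ± 0.21) and UBE2QL1 (-1.97 ± 0.13). As lists, p53 targets (adjusted p = 1.4e-42) and mesenchymal markers (adjusted p = 1.3e-08) lay toward HEK293 with Aza, and G2 and M phase genes toward U2OS with doxycycline (adjusted p = 4.1e-19). Aza was given at 880 nM in HEK293 and 55 nM in U2OS, so line and dose were not separable.

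Antisense transcription across VPS9D1 rose by 2.42 ± 0.16 with TET-CD (adjusted p = 9e-52) in the authors' deposited table, opposite to the fall of its sense transcript. NARFL (0.53 ± 0.18) and HDDC2 (0.47 ± 0.12) were also higher in antisense, and TET1 (-1.85 ± 0.07), ERC1 (-0.34 ± 0.06) and HIST1H1E (-0.32 ± 0.11) lower, in the authors' deposited table. With TETmut-CD the only antisense call was TET1 (-1.17 ± 0.07), and VPS9D1 stood at 0.02 ± 0.05 in the authors' deposited table. The constructs' antisense effects differed for VPS9D1 (2.06 ± 0.25, adjusted p = 9.3e-13), TET1 (-0.68 ± 0.10) and SLC46A1 (-0.42 ± 0.08). Antisense VPS9D1 rose with Aza in HEK293 (0.88 ± 0.19) without a called sense change (-0.08 ± 0.09), and in U2OS it was called with neither treatment, per the authors' deposited table. TET-CD gave 5 antisense calls in each direction at a median mean level of 6.69, far below that of sense transcripts.

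In U2OS, antisense signal over HIF1A, the hypoxia regulator, rose by 3.71 ± 0.19 with Aza and 2.50 ± 0.19 with doxycycline, with sense HIF1A at -0.05 ± 0.03 and -0.03 ± 0.03 in the authors' deposited table. FAHD1, a mitochondrial hydrolase gene, rose in antisense by 2.39 ± 0.23 and 2.38 ± 0.23, PROSER2 by 1.79 ± 0.19 with Aza, and the telomere protein gene TERF2IP by 1.88 ± 0.12 with doxycycline, in the authors' deposited table. Antisense PCDH9 (-0.85 ± 0.20), MARCH3 (-0.79 ± 0.11) and ST3GAL4 (-0.64 ± 0.22) fell with Aza, and TET1 (-1.90 ± 0.16), KSR1 (-0.56 ± 0.21) and IL1RAPL2 (-0.48 ± 0.14) with doxycycline, per the authors' deposited table. Aza gave 158 antisense genes higher and 142 lower, 194 and 103 after centring on the median gene, and doxycycline 87 and 31. In HEK293 with Aza, antisense STAMBPL1 (1.32 ± 0.19), NDUFAF6 (0.84 ± 0.24) and NCOA6 (0.79 ± 0.15) were higher in the authors' deposited table. Antisense IQCA1 (-0.82 ± 0.17), HK2 (-0.80 ± 0.23) and the cold shock gene CIRBP (-0.76 ± 0.10) were lower in the authors' deposited table. The split of 30 higher and 150 lower there rested on scaling: the median gene lay at -0.14, and after centring 44 were higher and 19 lower. Of 110 genes called in sense as well as antisense for U2OS with Aza, 22 were higher and 30 lower in each strand and 58 were opposite.

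UVA with thio raised RAPGEF3 by 1.62 ± 0.16 (adjusted p = 5.9e-23) and genes known as outputs of ERK signalling in the authors' deposited table: ETV5 (1.45 ± 0.20), SPRY4 (1.24 ± 0.13), DUSP6 (1.21 ± 0.10, adjusted p = 7.1e-31) and ETV4 (1.06 ± 0.09). CYP1B1, a target of the aryl hydrocarbon receptor (1.21 ± 0.14), AMOTL2, a Hippo pathway gene (0.97 ± 0.10), and the glycine transporter gene SLC6A9 (0.89 ± 0.13) were higher too in the authors' deposited table. The sterol gene INSIG1 (-0.73 ± 0.08) and the retinoid genes DHRS3 (-0.63 ± 0.09) and RARB (-0.61 ± 0.10) were lower in the authors' deposited table. PCOLCE (-0.63 ± 0.19), NCKAP1L (-0.59 ± 0.18), MLXIPL (-0.58 ± 0.26) and MYT1 (-0.57 ± 0.18) were also lower in the authors' deposited table. UVA alone changed ETV5 (1.24 ± 0.20), SPRY4 (1.06 ± 0.13), AMOTL2 (1.00 ± 0.10) and DUSP6 (0.89 ± 0.10) in the authors' deposited table. It also changed the actin regulator gene NCKAP1L (-0.97 ± 0.18), SEPP1 (-0.93 ± 0.23) and CRABP2 (-0.78 ± 0.23), in the authors' deposited table, but RAPGEF3 was not called (0.09 ± 0.13). Thio alone gave 6 calls, among them OGDH (0.19 ± 0.05) higher and the cold-inducible gene RBM3 (-0.36 ± 0.10), IDI1 (-0.29 ± 0.07) and HMGCS1 (-0.27 ± 0.07) lower, in the authors' deposited table. The counts were 757 higher and 582 lower with UVA and thio, 1028 and 720 with UVA, and 1 and 5 with thio. Those with thio became 1 and 2 at a mean level of at least 50, and 2 and 8 after centring. No antisense gene was called with thio, 0 by DESeq2. Of 17834 genes 415 had an unadjusted p below 0.05, a smaller share than no change at all would give.

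Cholesterol synthesis genes fell with UVA (17 of 24, 18 with 1 higher adjusted over the list alone, adjusted p = 3.9e-19). They fell with UVA and thio (1 higher and 17 lower, 1 and 18 adjusted over the list alone, adjusted p = 2.6e-23) and with thio (2 lower, 5 adjusted over the list alone, adjusted p = 4.6e-09). Genes of the integrated stress response fell with UVA alone (1 higher and 8 lower of 31, 3 and 15 adjusted over the list alone, adjusted p = 1e-05). With UVA and thio they rose (14 and 1, 20 and 1 adjusted over the list alone, adjusted p = 8.1e-13). ASNS, the asparagine synthetase gene, went from -0.36 ± 0.10 with UVA to 0.47 ± 0.10 with UVA and thio in the authors' deposited table. Immediate early genes rose with UVA (8 of 29, 11 with 1 lower adjusted over the list alone, adjusted p = 4.4e-05) and with UVA and thio (12, 13 adjusted over the list alone, adjusted p = 5.7e-18). Cytosolic ribosomal protein genes fell with UVA (17 of 81, 19 with 2 higher adjusted over the list alone, adjusted p = 7.2e-12). Clustered protocadherins rose with UVA and thio (16 of 49, 34 adjusted over the list alone, adjusted p = 6.9e-11). Neuronal genes rose likewise (4 of 28, 8 adjusted over the list alone, adjusted p = 0.00037), MAP2 by 0.52 ± 0.12 in the authors' deposited table. Histone genes were lower (10 of 70, 12 adjusted over the list alone, adjusted p = 9.9e-06).

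UVA with thio was also compared with each alone. Against UVA, RAPGEF3 (1.30 ± 0.15), CHAC1, a glutathione-degrading stress gene (1.18 ± 0.20), and SLC6A9 (1.14 ± 0.13) were higher and CA3 (-0.56 ± 0.18), KIAA1328 (-0.49 ± 0.11) and KCNIP2 (-0.47 ± 0.17) lower in the authors' deposited table. Against thio, RAPGEF3 (1.63 ± 0.16), CYP1B1 (1.16 ± 0.14) and DUSP6 (1.10 ± 0.10) were higher and RARB (-0.57 ± 0.10), FOXN4 (-0.53 ± 0.11) and DHRS3 (-0.51 ± 0.10) lower in the authors' deposited table. Of 31 integrated stress genes, 22 were higher against UVA (27 adjusted over the list alone, adjusted p = 2.2e-45). So were 7 p53 targets (12 adjusted over the list alone, adjusted p = 2.5e-17), CDKN1A by 0.49 ± 0.10 in the authors' deposited table. NRF2 targets were higher against thio (1 of 26, 4 adjusted over the list alone, adjusted p = 0.010) with a p of 0.095 at the correlation of 0.05. The counts were 197 higher and 220 lower against UVA (225 and 194 after centring) and 325 and 195 against thio. Departure from additivity of UVA and thio, an added test, was seen in CHAC1 (1.38 ± 0.27), RAPGEF3 (1.34 ± 0.22), SLC6A9 (1.15 ± 0.19), ARRDC4 (1.09 ± 0.13, adjusted p = 1.6e-12) and ASNS (1.04 ± 0.14). Smaller departures were those of the cystine transporter gene SLC7A11 (0.91 ± 0.16), TXNIP (0.80 ± 0.14) and DDIT3 (0.77 ± 0.14). In all 69 genes departed upward and 52 downward (32 and 20 from deposited shrunken values), and the integrated stress list lay upward (adjusted p = 3.2e-30).

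Antisense signal over DHX8 (0.99 ± 0.10), VWC2L (0.88 ± 0.24) and SPAG16 (0.83 ± 0.14) rose with UVA and thio in the authors' deposited table. Antisense GALNT9 (-0.85 ± 0.21), SRPK3 (-0.82 ± 0.19) and the cyclin gene CCNF (-0.65 ± 0.19) fell in the authors' deposited table. With UVA alone, VWC2L (0.91 ± 0.24), DHX8 (0.86 ± 0.10) and MARCH3 (0.75 ± 0.24) were higher and the kinase gene TLK2 (-0.47 ± 0.18) lower in antisense, per the authors' deposited table. Against thio, antisense SPAG16 (1.07 ± 0.14), DHX8 (1.04 ± 0.10) and VWC2L (0.98 ± 0.24) were higher and SRPK3 (-0.03 ± 0.06) was called lower despite the shrunken value, in the authors' deposited table. Against UVA, NRL (0.64 ± 0.18), PRKDC (0.63 ± 0.25) and MARS (0.60 ± 0.12) were higher and FAT2 (-0.80 ± 0.21), MARCH3 (-0.76 ± 0.23) and the glycosylase gene NEIL1 (-0.74 ± 0.19) lower in antisense in the authors' deposited table. Antisense counts were 13 higher and 18 lower with UVA and thio (20 and 11 after centring), 32 and 2 with UVA (22 and 3 after centring), and 12 and 1 against thio (7 and 1 after centring). They were 16 and 78 against UVA, where the median gene lay at -0.10 and centring gave 24 and 23.

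The MeBP experiment compared the MeBP_TET_WT line with the G16 and G37 clones of MeBP_TKO. Its labels conflict: MeBP_TET_WT samples carry the genotype TETMut-CD-GFP, and some samples numbered replicate 3 carry another line's genotype. In the MeBP_TET_WT line Aza raised GPR146 (2.04 ± 0.18), STAT6 (1.69 ± 0.16) and CRIP2 (1.44 ± 0.18) in the authors' deposited table. It lowered the synaptic scaffold gene DLGAP2 (-2.15 ± 0.24), GABBR2 (-1.04 ± 0.11) and CDH4 (-0.91 ± 0.25) in the authors' deposited table. In G16, the mitochondrial membrane gene TSPO (2.33 ± 0.30), CDH3 (1.92 ± 0.39) and GPR146 (1.66 ± 0.16) rose in the authors' deposited table. DLGAP2 (-2.47 ± 0.20), GABBR2 (-1.25 ± 0.12) and CDH4 (-1.03 ± 0.25) fell in the authors' deposited table. In G37, STAT6 (1.79 ± 0.16), GPR146 (1.67 ± 0.16) and OSTN (1.35 ± 0.16) rose and DLGAP2 (-1.95 ± 0.17), BTBD11 (-0.85 ± 0.11) and CDH4 (-0.82 ± 0.26) fell in the authors' deposited table. HAND1, a heart and trophoblast transcription factor gene, rose by 1.34 ± 0.13 in the MeBP_TET_WT line and by 0.38 ± 0.08 and 0.51 ± 0.08 in G16 and G37 in the authors' deposited table. Its direct difference was -0.95 ± 0.15 for G16 (adjusted p = 7.5e-06) and -0.83 ± 0.15 for G37 (adjusted p = 0.0011). TSPO differed by 1.77 ± 0.35 in G16, and so did MINOS1 (0.31 ± 0.06), SPTSSA (0.35 ± 0.08), LARP4 (0.20 ± 0.04), GXYLT1 (0.25 ± 0.06) and PTP4A1 (0.22 ± 0.05). These were all the differing genes from unshrunken values, 7 in G16 and HAND1 alone in G37. Deposited shrunken values gave 2 higher and 1 lower in G16, and 4 higher and 1 lower in G37. With Aza, 1708 genes were higher and 2024 lower in the MeBP_TET_WT line (2080 and 1467 after centring), 1956 and 2017 in G16 (2213 and 1729 after centring), and 2036 and 2119 in G37 (2209 and 1811 after centring).

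With Aza, p53 targets rose in the MeBP_TET_WT line (29 of 33, 30 adjusted over the list alone, adjusted p = 4.6e-42). They also rose in G16 (29, 30 adjusted over the list alone, adjusted p = 1.8e-49) and in G37 (26, 29 adjusted over the list alone, adjusted p = 2.4e-38). CDKN1A rose by 0.70 ± 0.07 in the MeBP_TET_WT line and by 0.71 ± 0.07 in each clone in the authors' deposited table. Genes of G2 and M phase rose in the MeBP_TET_WT line (14 of 30, 17 adjusted over the list alone, adjusted p = 1.1e-08) and in G37 (17, 19 adjusted over the list alone, adjusted p = 2.8e-06). In G16 they passed with 11 higher and 2 lower (14 and 3 adjusted over the list alone, adjusted p = 0.015), with a p of 0.12 at the correlation of 0.05. Directly, they lay lower in G16 than in the MeBP_TET_WT line (adjusted p = 7.7e-05, and 0.018 at the correlation of 0.05). In G37 the clustered protocadherins lay higher than in that line (adjusted p = 3.7e-10) and integrated stress genes lower (adjusted p = 9.0e-06). Polycomb target genes rose in G37 (12 of 32, 12 with 1 lower adjusted over the list alone, adjusted p = 0.0007). C2H2 zinc finger genes named ZNF passed there (69 higher and 26 lower of 500, 64 and 24 adjusted over the list alone, adjusted p = 0.037) with a p of 0.37 at the correlation of 0.05. Blood markers passed in G16 (2 of 15, 2 adjusted over the list alone, adjusted p = 0.048), where CSF1R was at 1.58 in the authors' deposited table, and the p was 0.15 at the correlation of 0.05. Among the methyl-binding protein genes followed in each comparison, MBD1 (-0.09 ± 0.14) and MBD2 (0.00 ± 0.10) were not called in G16 in the authors' deposited table. MBD3 was lower in G16 (-0.13 ± 0.05) and G37 (-0.16 ± 0.05), and ZBTB38, a methyl-binding zinc finger gene, was higher in G37 (0.24 ± 0.07), per the authors' deposited table. The tables compare treatments within a line, so no level of these genes between lines was available.

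Doxycycline raised TET1 by 2.52 ± 0.07 in the MeBP_TET_WT line, 1.97 ± 0.07 in G16 and 2.46 ± 0.07 in G37 in the authors' deposited table. VPS9D1 fell in each, by -0.74 ± 0.08, -0.58 ± 0.08 and -0.99 ± 0.09, and ERC1 rose, by 0.67 ± 0.06, 0.51 ± 0.06 and 0.66 ± 0.06, in the authors' deposited table. The MeBP_TET_WT line further had MXRA8 (1.60 ± 0.26) and FGD5 (1.05 ± 0.18) higher and the cation channel gene TRPC4 (-0.28 ± 0.10) and LHFPL4 (-0.26 ± 0.08) lower in the authors' deposited table. G16 had HIST1H2BG (0.42 ± 0.09) higher and MANEAL (-0.29 ± 0.05) and KIAA0513 (-0.28 ± 0.08) lower in the authors' deposited table. G37 had STAT6 (0.91 ± 0.18) and HSPA2 (0.69 ± 0.14) higher and MANEAL (-0.26 ± 0.05) and UQCRFS1 (-0.19 ± 0.04) lower, per the authors' deposited table. The counts were 159 higher and 40 lower in the MeBP_TET_WT line (204 and 24 after centring), 18 and 22 in G16 (45 and 21 after centring), and 39 and 6 in G37 (42 and 6 after centring). Directly, 48 genes were higher and 44 lower in G16 than in the MeBP_TET_WT line, among them GRINA (-0.71 ± 0.11), TET1 (-0.54 ± 0.10), MRPS2 (-0.43 ± 0.09), the ferritin gene FTL (-0.41 ± 0.07) and C11orf58 (0.19 ± 0.04). With deposited shrunken values the same comparison gave 1 higher and 12 lower. In G37, 0 of 15192 genes differed from that line by the z test on unshrunken values. Only 193 had an unadjusted p below 0.05, a smaller share than no difference at all would give. The standard errors were taken from the other lines. The result depends on these errors, since those of its own table gave 4 lower, and deposited shrunken values 1 higher and 29 lower. With the errors of the other lines, replication-dependent histones lay lower in G37 than in the MeBP_TET_WT line as a list (adjusted p = 4.3e-11, and 0.00016 at the correlation of 0.05). In G16, nuclear genes of oxidative phosphorylation (adjusted p = 0.0003) and genes of cholesterol synthesis (adjusted p = 0.0012) lay higher than in that line, each at 0.037 with the correlation of 0.05. On the TET-CD calls of HEK293, slopes were 0.838 (0.739 to 0.953) in the MeBP_TET_WT line, 0.462 (0.388 to 0.543) in G16, 0.639 (0.557 to 0.725) in G37 and 0.268 (0.118 to 0.475) in U2OS. The sign was that of HEK293 in 123, 122 and 126 of 131 genes in the 3 MeBP lines but in only 71 of 129 in U2OS. Integrated stress genes rose in the MeBP_TET_WT line (3 of 31, 4 adjusted over the list alone, adjusted p = 8.3e-07) and G37 (3, 5 adjusted over the list alone, adjusted p = 9.5e-11). Nuclear genes of oxidative phosphorylation passed as higher in G16 (adjusted p = 0.00023), without a called member and with 1 of 34 lower when adjusted over the list alone.

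In nascent RNA of HEK293, PRO-cap measured initiation and PRO-seq elongation, with sites given on hg19. No nascent RNA of the mutant construct was in the series, so an effect of doxycycline itself was not separated there. Aza raised initiation at CCDC80 (chr3:112360040-112360150, 1.11 ± 0.17), the immediate early gene EGR1 (chr5:137801160-137801270, 0.86 ± 0.11) and SLC9A7P1 (0.84 ± 0.16) in the authors' deposited table. It lowered initiation at HPCAL1 (chr2:10443020-10443140, -1.35 ± 0.34), NR2C1 (-1.06 ± 0.19) and RPS6KA1 (-1.03 ± 0.16) in the authors' deposited table. Doxycycline raised initiation at CCDC80 (0.85 ± 0.17), SPEF1 (0.84 ± 0.17) and TBX21 (0.84 ± 0.19) and lowered it at HPCAL1 (-1.10 ± 0.34), STK38 (-1.03 ± 0.28) and LSM12 (-1.02 ± 0.20) in the authors' deposited table. Elongation across EGR1 rose by 2.60 ± 0.19 with Aza (adjusted p = 8e-39) and 1.24 ± 0.19 with doxycycline in the authors' deposited table. FOS, another immediate early gene (1.44 ± 0.13), and SARDH (1.03 ± 0.16) rose with Aza, and TCHH (-1.02 ± 0.21), NKX6-1 (-0.98 ± 0.20) and the BMP antagonist gene NOG (-0.93 ± 0.15) fell, per the authors' deposited table. With doxycycline, MFSD4 (1.06 ± 0.24) and PPAPDC3 (1.00 ± 0.13) elongated more and FSTL3 (-1.01 ± 0.18), SH2D3C (-0.98 ± 0.16) and TRIB1 (-0.77 ± 0.20) less, in the authors' deposited table. Initiation was higher at 112 sites and lower at 147 with Aza and 114 and 112 with doxycycline, of 5846, and elongation at 279 and 309, and 129 and 98, of 3888 genes. Cytosolic ribosomal protein genes rose in initiation with Aza (7 of 23, 11 adjusted over the list alone, adjusted p = 5.9e-09) and doxycycline (5, 11 adjusted over the list alone, adjusted p = 3.7e-07). RPS19 rose by 0.54 ± 0.08 and 0.43 ± 0.08 in the authors' deposited table.

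Divergent initiation rose with Aza at WDR43 (0.77 ± 0.17), PGF (0.75 ± 0.18) and BEST2 (0.72 ± 0.17) and fell at SHC2 (-0.76 ± 0.15), ZFYVE20 (-0.75 ± 0.19) and NFIC (-0.74 ± 0.14) in the authors' deposited table. With doxycycline PGF, a placental growth factor gene (1.00 ± 0.18), SDC3 (0.93 ± 0.16) and FBLN1 (0.93 ± 0.16) were higher and SDHAP1 (-0.80 ± 0.25), ID3 (-0.79 ± 0.19) and ZFYVE20 (-0.70 ± 0.19) lower in the authors' deposited table. These were 100 higher and 92 lower with Aza and 114 and 65 with doxycycline, of 6022. Divergent elongation had 2 genes higher with Aza, and with doxycycline 0 by DESeq2. Of 2882 there, 61 had an unadjusted p below 0.05 with doxycycline, a smaller share than no change at all would give. Aza compared directly with doxycycline gave 5 lower initiation sites and 59 higher and 70 lower elongating genes. Divergent elongation gave 0 in that comparison by DESeq2, with 46 of 2882 at an unadjusted p below 0.05, again a smaller share than no difference would give. Changes with Aza and doxycycline correlated at 0.79 in initiation and 0.75 in elongation, where noise of the shared untreated libraries alone gave 0.476 and 0.502 in simulations. In initiation 50 higher and 59 lower sites were shared, against 17.7 and 21.2 simulated, and in elongation 85 and 81 genes, against 46.0 and 38.1. Since simulated sites carried no effect, only covariances are comparable. These were 0.0614 in initiation and 0.0438 in elongation, against at most 0.0162 and 0.00940 simulated.

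Start sites were given in classes. Primary start sites rose with Aza at PHYHIP (chr8:22085280-22085340, 1.19 ± 0.21), PCDP1 (1.08 ± 0.17) and FGF22 (0.86 ± 0.19) in the authors' deposited table. They fell there at the kinase gene STK40 (chr1:36851490-36851520, -1.44 ± 0.32), DAD1 (-1.27 ± 0.20) and SARS (-1.24 ± 0.37). With doxycycline primary sites rose at FBLN7 (1.14 ± 0.19) and PPAPDC3 (1.12 ± 0.18) in the authors' deposited table. They fell at STK40 (-1.22 ± 0.32), SARS (-1.17 ± 0.37) and CDK9 (-1.12 ± 0.38), in the authors' deposited table. Secondary sites rose with Aza at the p53 target AEN (chr15:89164631-89165380, 1.11 ± 0.22), WTIP (0.84 ± 0.16) and PTPRU (0.79 ± 0.17) in the authors' deposited table. They fell at DAPK3 (-1.22 ± 0.21), XPR1 (-1.07 ± 0.28) and MFSD5 (-0.94 ± 0.18) in the authors' deposited table. With doxycycline they rose at TNS3 (chr7:47621761-47622240, 1.25 ± 0.20), the retinoic acid hydroxylase gene CYP26A1 (1.14 ± 0.21) and WTIP (1.12 ± 0.15) in the authors' deposited table. They fell at FAM111B (-0.90 ± 0.21), PKNOX1 (-0.89 ± 0.18) and FAM98A (-0.87 ± 0.23), per the authors' deposited table. Intragenic sense sites rose with Aza in BIN1 (chr2:127822290-127822850, 0.69 ± 0.21), SRRM3 (0.65 ± 0.22) and GPRC5C (0.41 ± 0.13) in the authors' deposited table. They fell in SH2D3C (-1.18 ± 0.33), MYOM2 (-1.05 ± 0.23) and TEF (-1.01 ± 0.17) in the authors' deposited table. With doxycycline RIN3 (chr14:93153290-93153650, 1.21 ± 0.17), DLGAP3 (0.90 ± 0.16) and COL9A2 (0.83 ± 0.18) had higher intragenic sites in the authors' deposited table. SH2D3C (-1.24 ± 0.33) and TMEM134 (-0.85 ± 0.17) had lower ones, and that of MYOM2 fell by 1.00 ± 0.23, in the authors' deposited table.

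Divergent start sites rose with Aza at STARD8 (1.23 ± 0.23), FAM110D (1.13 ± 0.22) and CA4 (1.10 ± 0.20) in the authors' deposited table. They fell at the chaperonin gene CCT2 (-1.20 ± 0.38), ZBTB3 (-1.18 ± 0.20) and ZFYVE20 (-0.97 ± 0.26) in the authors' deposited table. With doxycycline FAM110D (chr1:26488250-26488800, 1.86 ± 0.21, adjusted p = 5.8e-15), SMOC2 (1.56 ± 0.23) and MFSD4 (1.49 ± 0.21) were higher and ZBTB3 (-0.94 ± 0.20), ZFYVE20 (-0.91 ± 0.26) and SERTAD1 (-0.82 ± 0.14) lower in the authors' deposited table. Antisense intragenic sites rose with Aza in the hair growth regulator HR (1.09 ± 0.18), the dipeptidase gene PEPD (0.93 ± 0.19) and PTMA (0.88 ± 0.13) in the authors' deposited table. They fell in RNF187 (-2.04 ± 0.53), ZNF703 (-1.22 ± 0.23) and ERN1 (-1.04 ± 0.22) in the authors' deposited table. With doxycycline PEPD (chr19:33952660-33953800, 1.37 ± 0.18, adjusted p = 2.7e-10), the potassium channel gene KCNN3 (chr1:154732890-154733360, 1.21 ± 0.23) and HR (1.08 ± 0.18) were higher in antisense in the authors' deposited table. The stress sensor gene ERN1 (-0.90 ± 0.22), ARRDC3 (-0.86 ± 0.22) and NT5M (-0.85 ± 0.23) were lower in the authors' deposited table.

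Among called primary sites, 35.2% were higher with Aza (305 and 562; 95% interval 32.0 to 38.5) and 39.4% with doxycycline (318 and 489; 36.0 to 42.9). With doxycycline a larger share was higher by Fisher's exact test at antisense intragenic sites, 73.5% (75 and 27; 63.9 to 81.8, adjusted p = 3.8e-10). Larger by that exact test were also the shares of secondary 59.5% (147 and 100; adjusted p = 8.0e-08), intragenic sense 58.9% (66 and 46; adjusted p = 0.000235) and divergent sites 57.0% (433 and 326; adjusted p = 4.4e-11). Dispersed antisense sites were higher in 10 of 10 calls with doxycycline (exact adjusted p = 0.0002). With Aza the dispersed classes stood apart by the same exact test, sense 95.7% (22 and 1; 78.1 to 99.9, adjusted p = 9.7e-09) and antisense 92.3% (24 and 2; 74.9 to 99.1, adjusted p = 9.7e-09). Divergent sites were at 42.0% with Aza (372 and 513; exact adjusted p = 0.00489), while secondary (35.3%, exact adjusted p = 1), intragenic sense (41.7%, 0.207) and antisense intragenic sites (42.4%, 0.104) did not pass against primary sites. Antisense intragenic sites did pass among calls at an adjusted p below 0.01, with 48.3% (43 and 46) against 29.0% at primary sites (exact adjusted p = 0.000977). Dispersed sense sites had 1 call with doxycycline (exact adjusted p = 0.431). In the deposited direct comparison of Aza with doxycycline, 0 of 5216 dispersed sense and 0 of 5550 dispersed antisense sites were called. The same comparison called 0 of 2934 antisense intragenic sites. A difference between the treatments was thus not shown at single sites of these classes. Neighbouring sites are not independent, which the exact test ignores, and a share of calls depends on each class's mean level.

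**Figure D4:**
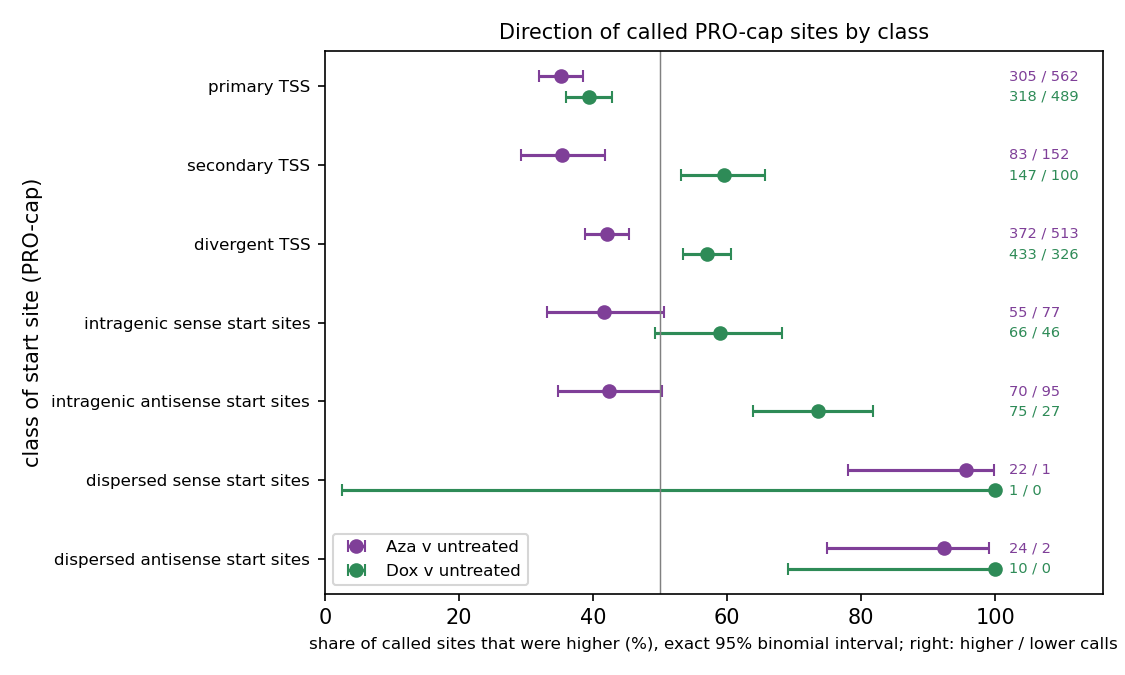
Percent of called start sites that were higher in each class, with exact 95% intervals, for Aza and doxycycline.

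The nascent and steady-state changes were matched by gene. EGR1, the tyrosine kinase gene SRC, AEN, RPS19 and HAND1 rose in initiation and elongation with Aza, HAND1 by 0.94 ± 0.27 and 0.83 ± 0.21 and SRC by 0.58 ± 0.10 and 0.36 ± 0.07 in the authors' deposited table. With doxycycline CTSH rose by 0.57 ± 0.15 in initiation and 0.78 ± 0.15 in elongation in the authors' deposited table, as its total RNA did. Over 3440 genes the initiation and elongation changes had a Spearman correlation of 0.314 with Aza and 0.445 with doxycycline. Between elongation and total RNA it was 0.274 (0.232 to 0.315) with Aza and 0.201 (0.161 to 0.242) with doxycycline, and between initiation and total RNA 0.0915 (0.0539 to 0.135) and 0.109 (0.0680 to 0.148). Initiation correlated no less with the total RNA of the other treatment, 0.0944 with Aza and 0.125 with doxycycline, while elongation gave 0.0630 and 0.161 there. With Aza 92 genes were higher and 39 lower in elongation and total RNA, against 22.8 and 18.7 for independent calls, and 20 moved in opposite directions. With doxycycline 15 were higher, against 1.10. Of the 7 lower DESeq2 calls in total RNA 0 were among the 70 in elongation, where independent calls give only 0.163. Steady-state RNA also reflects decay, which was not measured.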

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

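Of the tests weighed here, the covariance between nascent changes and the correlation of initiation with total RNA were chosen only after their result was seen, and the others were written down before.

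The results below were singled out because effects of the same treatment differed between constructs, cell lines or clones in a direct test. TET-CD and TETmut-CD differed in 25 sense genes, among them VPS9D1 at -0.78 ± 0.11, and in 3 antisense genes, with VPS9D1 at 2.06 ± 0.25. HEK293 and U2OS differed in 366 genes with doxycycline, with TES at -2.37 ± 0.17, and in 1964 genes with Aza, with STAT6 at 1.83 ± 0.17. With Aza the G16 clone differed from the MeBP_TET_WT line in 7 genes, with TSPO at 1.77 ± 0.35, and the G37 clone in 1 gene, HAND1, at -0.83 ± 0.15. With doxycycline G16 differed in 92 genes, with GRINA at -0.71 ± 0.11, but in 13 with deposited shrunken values. The genotype labels of this experiment conflict, and a wrong label remains possible for the values of MeBP_TET_WT, G16 and G37.

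More genes were called with TET-CD than with TETmut-CD. Lower precision of the TETmut-CD comparison was weighed first: over TET-CD calls the TETmut-CD slope was 0.00489, with an upper bound of 0.0821, below the slope of 0.838 (lower bound 0.739) in the separate MeBP_TET_WT line, so imprecision is excluded as the whole cause. This pattern may therefore reflect the mutation that separates the constructs by their labels, but TET1 itself rose by 0.36 ± 0.04 more with TET-CD, and a difference in dose of the construct was not tested. The genotype label of MeBP_TET_WT names the mutant construct, yet 123 of 131 genes had the sign of the TET-CD change in that line, against 83 with TETmut-CD. The slope of 0.838 there, against 0.00489 with TETmut-CD, argues against the mutant construct in that line, over these genes. No sample was reassigned from its values, and the labels of single replicates are left open.

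Higher calls outnumbered lower ones in some start-site classes. The low mean level of these sites fits: primary sites weighted to the same levels had 88.6% higher calls for the dispersed sense class with Aza, 91.1% for the dispersed antisense class, and 67.8% for intragenic antisense sites with doxycycline, each inside the interval of its class. An offset of the median site is not the whole cause, since those medians already lay near 0 (0.0069, 0.0079 and 0.010). After centring the lower bounds of these shares were 78.1%, 74.0% and 62.1%. Centred primary shares were 31.5% with Aza and 37.3% with doxycycline. Centring cannot test a scaling bias that varies with mean level, so scaling of that kind is left open. For these 3 classes the shift could thus follow mean level (88.6% against 95.7%) rather than the kind of site. Divergent sites with doxycycline, at 57.0% against 39.4%, had a median mean level of 119 against 112 at primary sites, but level matching was not run for that class and its shift is left open.

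Nascent changes with Aza and doxycycline ran alike at primary sites, where 145 were higher and 369 lower with each. Noise of the shared untreated libraries is excluded as the whole cause, because the covariance of 0.1003 exceeded the highest of the simulated values, 0.0168. Untreated libraries that stand apart from the treated ones remain possible. In the test of this, chosen in place of elongation after the elongation value of 0.201 had been seen, initiation and total RNA changes with doxycycline had a Spearman correlation of 0.109 (0.0680 to 0.148), which decides nothing against a limit of 0.1. A shared effect of Aza and doxycycline, given to separate cells, might equally produce the covariance of 0.1003. Without nascent RNA of the mutant construct, an effect of doxycycline itself was not separated from that of TET-CD.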

How the results depend on the processing

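The planned input of difference tests was the deposited values, which are kept here as an alternative. Undoing the shrinkage, used in the main tests, and the standard errors for G37 with doxycycline were chosen only after the data had been seen. Of 181 alternatives to the main results, 156 were labelled unchanged, and of 756 alternatives for named genes 11 lost the call. For a count of calls, unchanged meant a total within 1.5 times, whatever the split between higher and lower. The larger direction still turned in some of these, as in U2OS with Aza, from 1895 higher and 2266 lower to 2095 and 2072 after centring. Centring also turned it with doxycycline in U2OS and with Aza in the 3 MeBP lines. For each change listed here the cause was not tested. Adjustment over every gene with a p gave 6 antisense calls with TET-CD, 103 with Aza in HEK293, 17 with UVA and thio, 13 with UVA, and 5 and 36 for UVA with thio against thio and against UVA. A mean level of at least 50 left 3 calls with thio. Centring gave 10 sense calls with thio, 63 antisense calls with Aza in HEK293, 8 and 47 antisense calls for UVA with thio against thio and UVA, and 66 calls in G16 with doxycycline.

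With deposited shrunken values 45 genes differed between TET-CD and TETmut-CD, 3 between G16 and MeBP_TET_WT with Aza and 13 with doxycycline, 5 and 30 between G37 and MeBP_TET_WT, and 52 departed from additivity of UVA and thio. With the standard errors of its own table, 4 genes differed for G37 with doxycycline. At a mean level of at least 50 the correlation of sense and antisense changes was 0.0188 with TETmut-CD and 0.0270 for UVA with thio against thio, and it reversed to -0.0511 with Aza in HEK293 (0.0309 over all genes). At an adjusted p below 0.01, 48.3% of antisense intragenic sites were higher with Aza against 29.0% of primary sites, a difference that then passed (adjusted p = 0.000977). After centring, 31.2% of secondary sites were higher with Aza, reversed relative to primary sites at 31.5%. Of 194 list tests past the threshold, 102 remained at a correlation of 0.05 and 170 on ranks, with 0 in the other direction.

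No paired analysis was possible because the tables carry no per-sample columns. For the same reason a fit with edgeR or DESeq2, a filter on low counts, leaving out a library, a replicate block and another pseudocount were planned or considered but not run. Antisense transcripts and dispersed sites have median mean levels of 4.98 to 9.20, far below those of sense transcripts.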

Other observations

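Among the tests below, those of MBD1 and MBD2 and of ERK output were chosen only after the result was seen, and that of retinoic acid targets before.

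Some genes followed the same course in separate experiments. HAND1 rose with Aza by 1.87 ± 0.22 in HEK293 total RNA and with doxycycline by 0.59 ± 0.15 in the MeBP_TET_WT line, in the authors' deposited table. Histone HIST1H2BG rose with Aza in HEK293 (0.94 ± 0.12) and U2OS (1.21 ± 0.09) and with doxycycline in U2OS (0.71 ± 0.10) and the MeBP_TET_WT line (0.81 ± 0.09), but not with TETmut-CD, in the authors' deposited table. Doxycycline in the MeBP_TET_WT line shared 58 higher genes with TET-CD in HEK293, where independence gives 1.03, and 5 lower ones, where it gives 0.0913. Aza in HEK293 and in the MeBP_TET_WT line shared 872 higher and 855 lower genes and had 0 opposite ones, with a correlation of 0.83 between separate sets of libraries, while HEK293 and U2OS with Aza shared 293 and 278 and had 217 opposite ones.

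Changes with Aza and with UVA in HEK293 had a correlation of -0.03, with 77 genes higher and 85 lower in each and 163 opposite. Noise of their shared untreated libraries alone gave 0.492 in simulations, with 286 and 248 shared. Those simulated genes carried no effect, so these figures are not comparable with the data. The covariance was -0.00109, against 0.00494 simulated with an assumed share of noise, so apart from such noise the changes did not run alike. The list of NF-kB cytokines rose with Aza in U2OS (6 higher and 1 lower of 23, 8 and 2 adjusted over the list alone, adjusted p = 0.00091), and nuclear genes of oxidative phosphorylation fell with TETmut-CD (1 of 34, 1 adjusted over the list alone, adjusted p = 0.0024) with a p of 0.068 at the correlation of 0.05. The cytosine methylation machinery with doxycycline in G16 had a mean z of 0.64 and a median z of -0.31 (adjusted p = 0.026, and a p of 0.23 at the correlation of 0.05). TET1, raised by doxycycline there, is a member of that list, so this pass says nothing of the remaining genes either. Histones with doxycycline in the MeBP_TET_WT line had a mean z of 0.43 and a median z of -0.12 (3 of 70 higher, 3 adjusted over the list alone, adjusted p = 0.049, and a p of 0.33 at the correlation of 0.05).

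MBD1 and MBD2 had wide standard errors in G16, with ratios to the MeBP_TET_WT line from 3.85 to 4.25, where the 99th percentile over 11380 genes was 1.05 with Aza. These were the widest ratios among genes with a mean level of at least 300. In G37 with Aza the ratio was 2.57 for MBD2 and 1.09 for MBD1. Whether few reads from these genes lie behind the widths could not be decided, since the ratios were themselves the observation and levels per line were not used here.

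ETV4, ETV5, SPRY4 and DUSP6 rose with UVA and thio. The other 20 measured genes of an ERK output list gave a list test p of 3.6e-17, not adjusted over lists. They were higher as a list (9 higher, 12 adjusted over the list alone). That is in line with higher ERK pathway output, as far as a p of 3.6e-17 over genes picked for that pathway goes, and no protein was measured.

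DHRS3 fell with UVA by 0.43 ± 0.10 in the authors' deposited table, whereas RARB was called only where thio was given with UVA. Lower retinoic acid signalling could not be decided: the other 21 targets gave a list p of 0.795 with UVA, with a mean z of -0.04 and a median z of 0.29. A p of 0.05 or more had been written down beforehand as counting against the idea, which was wrong, since it excludes nothing when members go in either direction, CRABP2 (-0.78) and CYP26A1 (-0.25) lower and MEIS2 (0.28) higher in the authors' deposited table.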
